A study of Mus musculus with 16 samples.

How the data were processed

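The study measured total RNA of pancreatic islets from 16 mouse samples, 7 labelled Cre+T and 9 labelled Cre-T, taken 6 days after tamoxifen per the labels. RNA was extracted with a column kit with DNase treatment, and libraries were made with an Illumina TruSeq kit and sequenced on a HiSeq 2500 in 150 bp pairs, per the labels' protocols. Reads were aligned with TopHat2 to GRCm38 and the genes were tested with limma, per the submitters' processing notes, which give no versions. The counting tool, the filter on low genes and the samples that entered the fit are not given in the sources used here.

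The deposited table held 1 row for each of 10208 genes and no values per sample. The authors gave a log2 fold change, a mean expression on the log2 scale, a moderated t score with a log-odds score, a p-value, an adjusted p-value and a q-value, per the file headers. The deposited results are named as output of voom and limma, so the mean was read as log2 CPM, scaled by library size. The adjusted p-value was checked to be the Benjamini-Hochberg value over these rows. The q-value in the deposited table was 0.325 times the adjusted p-value in each row. The p-values follow from the moderated t at 16.1 degrees of freedom in each row tested. All 16 labelled samples in 2 groups would leave 14 residual degrees of freedom before limma adds its prior, so the number is compatible with a fit of all of them without proving it. The header does not name the direction of the fold change. It was read as Cre+T over Cre-T because Ins2 was negative and Esr1, part of the CreERT fusion, was strongly positive. In the deposited table, 17 rows carried a whole number in place of a symbol, as spreadsheets leave when they read a name as a date, and 2 names were held by more than 1 row, where the row with the highest mean was used. Gene IDs were matched without version to GENCODE release M21, which is on the same build; 10190 matched and 18 did not.

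Standard errors were computed as the size of the log2 fold change divided by t, and 95% intervals from them with 16.1 degrees of freedom. Limma estimates the variance of each gene from the samples of a fit, so these errors cover the spread between the samples of the authors' fit. No mean, SD or n per group could be computed, the number of samples that show a direction could not be counted, and no sample could be left out in turn. The depth per sample is unknown, and the labels state only 20000000 read pairs per sample.

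Before the data were examined, designs were fixed for tables with and without values per sample, and the second applied. Genes were counted as changed at the authors' adjusted p under 0.05. The 30 gene lists were fixed then as well. Those with at least 5 measured genes, 27 in all, were tested two-sided with cameraPR of limma 3.58.1 in R 4.3.3, which compares the t of a list with that of all other genes, at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 27 lists. A correlation estimated from samples could not be had, so 0.05 was used beside it. Genes of 1 list can vary together by more than either value, so the p-values of lists may be too small. For each list the genes past the threshold were counted over all genes and adjusted over the list alone. The genes named were Ins2, Ins1 and Pdx1, the 10 largest rises and 10 largest falls with an adjusted p under 0.05 and a mean of at least 1 log2 CPM, leaving out predicted models, and the 4 genes of each list with the smallest p. Some genes that this rule takes are not reported here. Other genes named were chosen after their values were seen.

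Alternatives were other thresholds of the adjusted p (0.01 and 0.1), genes at or above the median mean expression, genes with a mean of at least 1, a minimum fold change, Holm adjustment and 1 row per symbol. For the list tests they were ranks, fold change in place of t, the higher correlation and another background. After the data were seen, the authors' q-value and 2 other scalings were added. One set the summed expression of both groups equal, and the other set the median ribosomal protein gene to 0. The sums were of group means of log2 values taken back to the linear scale. They were estimated from the authors' means and fold changes with groups of 7 and 9. Such sums can differ between groups where the total of counts does not, so this scaling shows the dependence on a shift and no true total. The list tests were also repeated after removal of a quadratic trend of t with mean expression, longest transcript length and its GC content, and without the acinar genes in the background. Medians with the trend removed came from a separate fit of the same form to the fold changes. Shifted fold changes were divided by the same standard errors.

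The calls were tested on simulated data for this comparison over all 10208 genes, with the table's own standard errors and 200 changed genes, 100 of each size. Changes of 0.5 log2 units were recovered in 60% of genes and changes of 1 log2 unit in 83%, and 8.33% of the calls were false. All 3 shifted lists were recovered with 0 other lists called, and 4 of 100 shuffles of t gave any call of a list. The noise was independent between genes, and 200 changed genes are far fewer than the 37.6% called in the data. The recovered and false shares therefore need not hold for the data. Shuffling t over genes also breaks their correlation, so it cannot show how often lists of genes that vary together are called. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.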

Results

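RNA was sequenced from pancreatic islets of adult mice that lacked Ins1 and carried a loxP-flanked Ins2, the other mouse insulin gene. Tamoxifen was given 6 days before islet isolation. It activates CreERT, a recombinase fused to a mutated oestrogen receptor domain, driven here by Pdx1 regulatory sequence. The 16 samples were labelled Cre+T (7 samples) and Cre-T (9 samples). The labels gave all of them the same genotype string and a mixed, mostly C57Bl/6 background. That string includes Pdx1CreERT for both groups, and the labels do not say whether Cre-T mice carried the transgene. The libraries were made from total RNA and read as 150 bp pairs, at 20000000 pairs per sample according to the labels. The sample titles begin with 6 different numbers that the labels do not explain. Only 2 of them hold samples of both groups, 7 samples in all, and the other 9 samples lie under numbers with 1 group each, so a difference between numbers would be largely confounded with the groups. The depth of single samples is unknown here, since only the authors' table of limma results was analysed, with 10208 genes and no values per sample. Its mean expression ran from 0.22 to 16.34 log2 CPM, with a median of 5.21 in the authors' deposited table. The labels do not say whether each sample was a separate animal, so the p-values measure the spread between these samples, part of which may be technical. Fold changes are Cre+T over Cre-T, and errors are standard errors derived from the authors' fold change and moderated t.

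Islets labelled Cre+T were compared with islets labelled Cre-T, in a design meant to delete Ins2. The table does not name the direction of its fold changes, which was read from the negative sign of Ins2 and the positive sign of Esr1. That Ins2 was lower and Esr1 higher in Cre+T is therefore assumed here and is no test of the deletion or the labels. Ins2 was the gene with the highest mean expression, and read this way it stood at 0.723 of the Cre-T level in the authors' deposited table. This is a log2 fold change of -0.47 ± 0.17 with a limma adjusted p of 0.041 in the authors' deposited table, and the 95% interval of the fold was 0.564 to 0.929. Ins2 (ENSMUSG00000000215.5) is annotated on chromosome 7 from 142678656 to 142743381 in GENCODE release M21 on GRCm38. The labels do not name the deleted part, and the table gives 1 value for the gene as a whole, so reads from transcripts that had lost only part of the gene would still count. Ins1 had no row and was not analysed here. Pdx1, a transcription factor of beta cells whose regulatory sequence drove CreERT, rose 1.49-fold, with a log2 fold change of 0.57 ± 0.11 and a limma adjusted p of 0.0013 in the authors' deposited table. It lies on chromosome 5 from 147269959 to 147275848. Esr1, the oestrogen receptor gene whose domain is part of CreERT, had the highest fold change of all genes named here, 9.30 ± 0.39 on the log2 scale in the authors' deposited table (limma adjusted p = 5.4e-10). A fitted fold change of this size depends on the offset added to low counts and is no bound on the true ratio. Esr1 is annotated on chromosome 10 from 4611593 to 5005614, and reads from the transgene and from the gene itself cannot be told apart in a value per gene. The labels give CreERT to both groups. If the Esr1 reads come from the transgene, a difference of this size argues against a like expression of CreERT in both.

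At a limma adjusted p under 0.05, 1794 genes were higher and 2049 were lower in Cre+T, together 37.6% of the authors' deposited table. Of these, 248 were higher and 130 lower by at least 1 log2 unit in the authors' deposited table. The split depended on scaling. Where the fold changes were shifted by 0.14 log2 units so that summed expression was equal in both groups, 860 genes were higher and 3934 lower, which took the share of higher genes from 46.7% to 17.9%. That sum was built from group means of log2 values and not from counts, so the shift need not reflect a difference in total counts. With the median ribosomal protein gene set to 0, 1393 were higher and 2591 lower, a share of 35.0%. Changes below are relative to the authors' scaling. Markers of several other cell types were higher in Cre+T, as given below, and the table does not show in which cells a change took place.

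After Esr1, the largest rises among genes with a mean of at least 1 log2 CPM included several genes of exocrine pancreas, liver or blood in the authors' deposited table. Itih4, a secreted protein of liver and pancreas, rose by 4.26 ± 1.56, and Ly6c1, a surface antigen of endothelial cells and leukocytes, by 3.95 ± 1.50 log2 units in the authors' deposited table. The acinar water channel gene Aqp12 rose by 3.79 ± 1.30 in the authors' deposited table. Rbpjl, an acinar transcription factor, rose by 3.70 ± 1.33, and the zinc transporter gene Slc39a5 by 3.33 ± 1.09 in the authors' deposited table. The alpha-globin genes Hba-a2 (3.42 ± 1.10) and Hba-a1 (3.32 ± 1.02) also rose in the authors' deposited table, and their values are uncertain because near-identical copies share reads. Limma adjusted p lay between 0.019 and 0.048 for these 7 genes in the authors' deposited table. Bend5 on chromosome 4, from 111415006 to 111460298, rose by 3.36 ± 0.23 log2 units with a limma adjusted p of 6.2e-07, which ranked 2 among all genes in the authors' deposited table. The acinar markers described below, with a median of 2.37 log2 units in the authors' deposited table, rose in the same comparison.

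Angptl6, an angiopoietin-like secreted protein, had the largest fall by the rule for named genes, with a log2 fold change of -3.33 ± 0.36, which is 0.0991 of the Cre-T level in the authors' deposited table. The cytochrome P450 gene Cyp4f39 followed at -3.22 ± 0.41, and Aldh1l2, a mitochondrial enzyme of folate metabolism, at -2.96 ± 0.40 in the authors' deposited table. The growth factor genes Areg (-2.68 ± 0.61) and Gdf15 (-2.44 ± 0.33) fell, as did the peptide hormone gene Adm2 (-2.64 ± 0.37) and the cytokine gene Il11 (-2.61 ± 0.60) in the authors' deposited table. The metalloreductase gene Steap1 (-2.66 ± 0.26), the tachykinin receptor gene Tacr3 (-2.36 ± 0.80) and the serum thyroxine carrier gene Serpina7 (-2.35 ± 0.31) completed the 10 in the authors' deposited table. Their limma adjusted p lay between 2.8e-05 and 0.030 in the authors' deposited table. Areg and Tacr3 were near the low end of expression, with mean log2 CPM of 1.58 and 1.37.

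**Figure D1:**
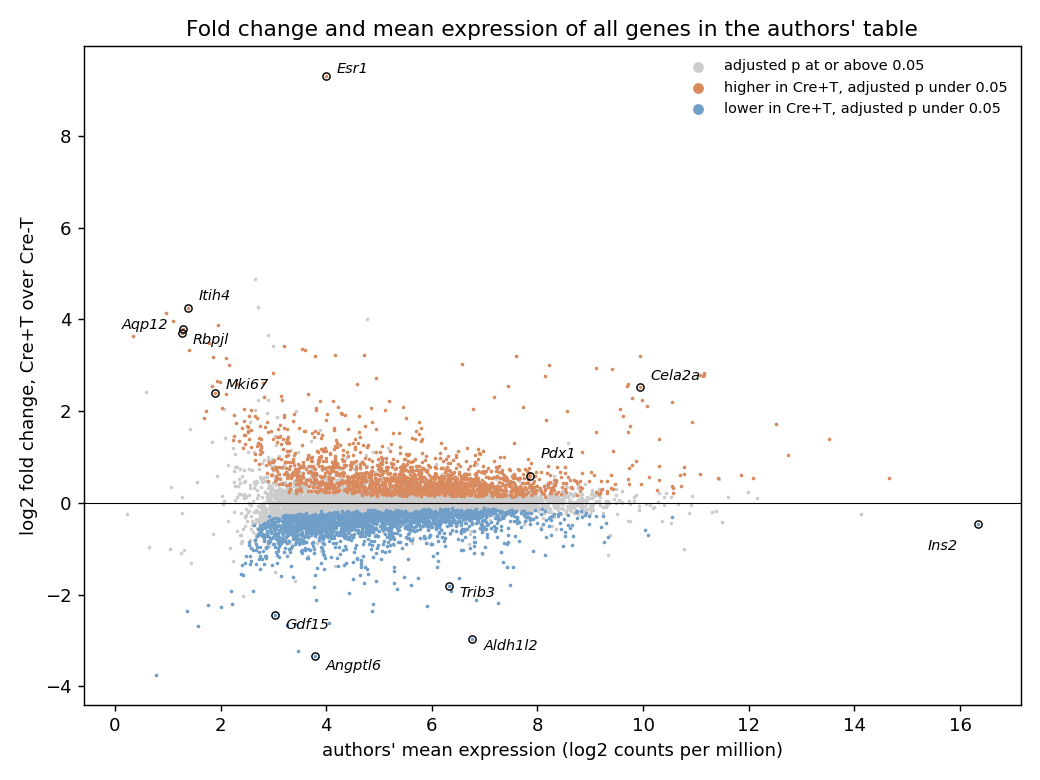
Log2 fold change of Cre+T over Cre-T (vertical axis) against the authors' mean expression in log2 CPM (horizontal axis), 1 point for each of the 10208 genes in the authors' deposited table, coloured by whether the limma adjusted p was under 0.05 and by direction. Esr1 stands at 9.30, Ins2 at -0.47 at the right edge, and Angptl6 at -3.33, with some of the genes named in the text circled.

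A list was drawn up for the kinase PERK, the transcription factor ATF4 and the targets of ATF4 in the unfolded protein response. Most of its genes were lower in Cre+T, and the values do not show whether PERK or another signal lowered them. Of 23 measured genes of this list, 19 fell, 1 rose and 3 did not pass in the authors' deposited table, with a median log2 fold change of -0.78. The counts adjusted over the list alone were also 19 and 1 in the authors' deposited table. The 4 genes with the smallest p were Trib3, a pseudokinase induced by ATF4, at -1.82 ± 0.19, Sesn2, a stress-induced regulator of mTORC1, at -0.75 ± 0.10, Aldh1l2, and the amino acid transporter subunit gene Slc3a2 at -0.35 ± 0.05 in the authors' deposited table. Genes of serine and folate metabolism in the list, picked after their values were seen, fell as well: Psat1 by 1.64, Phgdh by 1.03 and Shmt2 by 1.65 log2 units in the authors' deposited table. Atf4 itself fell by 0.27 and Ddit3, which encodes CHOP, by 1.11 log2 units in the authors' deposited table. Eif2ak3, which encodes PERK, did not pass (0.15 ± 0.12, limma adjusted p = 0.34) in the authors' deposited table. The 1 gene that rose was Atf3, at 1.16 ± 0.32 in the authors' deposited table, which is also an immediate early gene. Against all other genes of the authors' deposited table the list had a cameraPR adjusted p of 3.7e-11, and of 1.7e-06 at an inter-gene correlation of 0.05. Targets of 1 factor can vary together and their correlation could not be estimated, so both values may be too small.

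Chaperones of the endoplasmic reticulum and its degradation machinery moved both ways. Of 30 measured genes, 6 rose, 6 fell and 18 did not pass in the authors' deposited table, or 7 and 7 adjusted over the list alone. Ero1lb, the oxidase that is abundant in beta cells, rose by 0.77 ± 0.14, while its paralogue Ero1l fell by 1.04 log2 units with an error of 0.27 in the authors' deposited table. Ern1, which encodes the stress sensor IRE1-alpha, was at -0.56 ± 0.08 and Derl1, a component of the export channel, at -0.37 ± 0.09, both lower in the authors' deposited table. The chaperone gene Hspa5 (BiP), picked after its value was seen, rose by 0.55 ± 0.18 in the authors' deposited table. The list's median was -0.03 and its mean 0.01, so they differed in sign, and its cameraPR adjusted p was 0.91 on the authors' deposited table. With summed expression made equal, 1 gene of the list was higher and 11 were lower. Of 28 genes of translocation and signal peptide processing, 2 rose and 3 fell, the same numbers as adjusted over the list alone in the authors' deposited table (median -0.03, cameraPR adjusted p = 0.91). They were Kdelr2 (-0.31 ± 0.08), Lman1 (-0.32 ± 0.08) and Srpr (-0.18 ± 0.06), which fell, and Ssr4 (0.28 ± 0.08) and Spcs1 (0.24 ± 0.08), which rose in the authors' deposited table. Ssr4 no longer passed with summed expression made equal (adjusted p = 0.17), and of this list no gene was then higher and 9 were lower. Acinar markers, whose cells are also rich in this machinery, rose in the same samples, with a median of 2.37 log2 units in the authors' deposited table.

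Genes of the cell cycle were thinly covered. Of 37 genes of S, G2 and M phase fixed for the comparison, 10 had a row, of which 2 rose and 8 did not pass in the authors' deposited table, also when adjusted over the list alone. The proliferation marker Mki67 rose 5.29-fold (2.40 ± 0.39 log2 units, limma adjusted p = 5.7e-04) and the topoisomerase gene Top2a 6.21-fold (2.64 ± 0.53, limma adjusted p = 0.0023) in the authors' deposited table. Markers of acinar cells (median 2.37), leukocytes (1.28) and red blood cells (3.37) were higher in the same comparison in the authors' deposited table, and the table does not show which cells expressed Mki67 and Top2a. Both were near the low end of expression, with mean log2 CPM of 1.89 and 1.98 in the authors' deposited table. The replication helicase genes Mcm7 (-0.46 ± 0.18) and Mcm4 (0.20 ± 0.09) did not pass in the authors' deposited table. The list's median was 0.06, and -0.08 with summed expression made equal, and its cameraPR adjusted p was 0.26 on the authors' deposited table. The list passed with fold change in place of t (adjusted p = 0.014, in a range of 0.014 to 0.37 over the alternatives). Among 15 measured cyclins, kinases and inhibitors of G1 phase, 2 rose and 6 fell, or 3 and 8 adjusted over the list alone in the authors' deposited table (median -0.21, cameraPR adjusted p = 0.11). The kinase inhibitor gene Cdkn2b fell most clearly, at -0.71 ± 0.11, followed in p by Cdk4 (-0.27 ± 0.06), Rbl2 (-0.47 ± 0.11) and Rbl1 (-0.48 ± 0.12), both of the retinoblastoma family, in the authors' deposited table. Ccnd1 (0.33 ± 0.12) and Cdkn2d (0.36 ± 0.11) were the 2 that rose in the authors' deposited table, and with summed expression made equal none of the list was higher and 10 were lower.

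Some genes that define beta cells were higher, and the call of the list depended on the setting. Of 26 transcription factors and functional genes, 10 rose, 1 fell and 15 did not pass, or 11 and 2 adjusted over the list alone in the authors' deposited table (median 0.27). The prohormone convertase gene Pcsk1 rose 1.89-fold (0.92 ± 0.12), the maturity marker Ucn3 by 0.87 ± 0.17, and the amylin gene Iapp by 0.54 ± 0.10 log2 units in the authors' deposited table, beside Pdx1 above. Isl1, at -0.39 ± 0.10, was the 1 that fell in the authors' deposited table. Of 22 genes of secretory granules and exocytosis, 8 rose, none fell at a limma adjusted p under 0.05, and the counts adjusted over the list alone were equal to these in the authors' deposited table (median 0.18). The granins Chga (1.39 ± 0.18) and Scg2 (1.04 ± 0.13) led, with the carboxypeptidase gene Cpe (0.55 ± 0.11) and Resp18 (0.50 ± 0.10) in the authors' deposited table. CameraPR adjusted p was 0.0038 for the beta-cell list and 0.0060 for the granule list on the authors' deposited table. Both calls were lost at an inter-gene correlation of 0.05, with adjusted p of 0.056 each, and after removal of a trend with expression level, transcript length and GC content, with adjusted p of 0.093 and 0.26. The trend took the medians from 0.27 to 0.14 and from 0.18 to 0.03, and the ranges over the alternatives were 6.8e-04 to 0.093 and 0.0023 to 0.26. With summed expression made equal, 7 genes of the beta-cell list were higher and 3 lower, and 7 of the granule list were higher and 6 lower.

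Markers of other islet endocrine cells had no call as a group, and their difference from the beta-cell list was not tested. Of 14 measured markers, 1 rose, 3 fell and 10 did not pass in the authors' deposited table, also when adjusted over the list alone (median -0.20, cameraPR adjusted p = 0.73). Transthyretin, Ttr, rose by 1.88 ± 0.26, while the peptide gene Pyy (-0.69 ± 0.18) and Etv1 (-0.89 ± 0.22) were among those that fell in the authors' deposited table. Of 15 measured genes of progenitors or genes normally silent in beta cells, 1 rose and 1 fell, or 1 and 0 adjusted over the list alone in the authors' deposited table (median 0.44, cameraPR adjusted p = 0.31). Npy rose by 1.80 ± 0.44 and Cat, catalase, was lower at -0.60 ± 0.23, while Smad3 (0.84 ± 0.37) and Sox9 (1.11 ± 0.49), which is also on the ductal list, did not pass in the authors' deposited table.

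**Figure D2:**
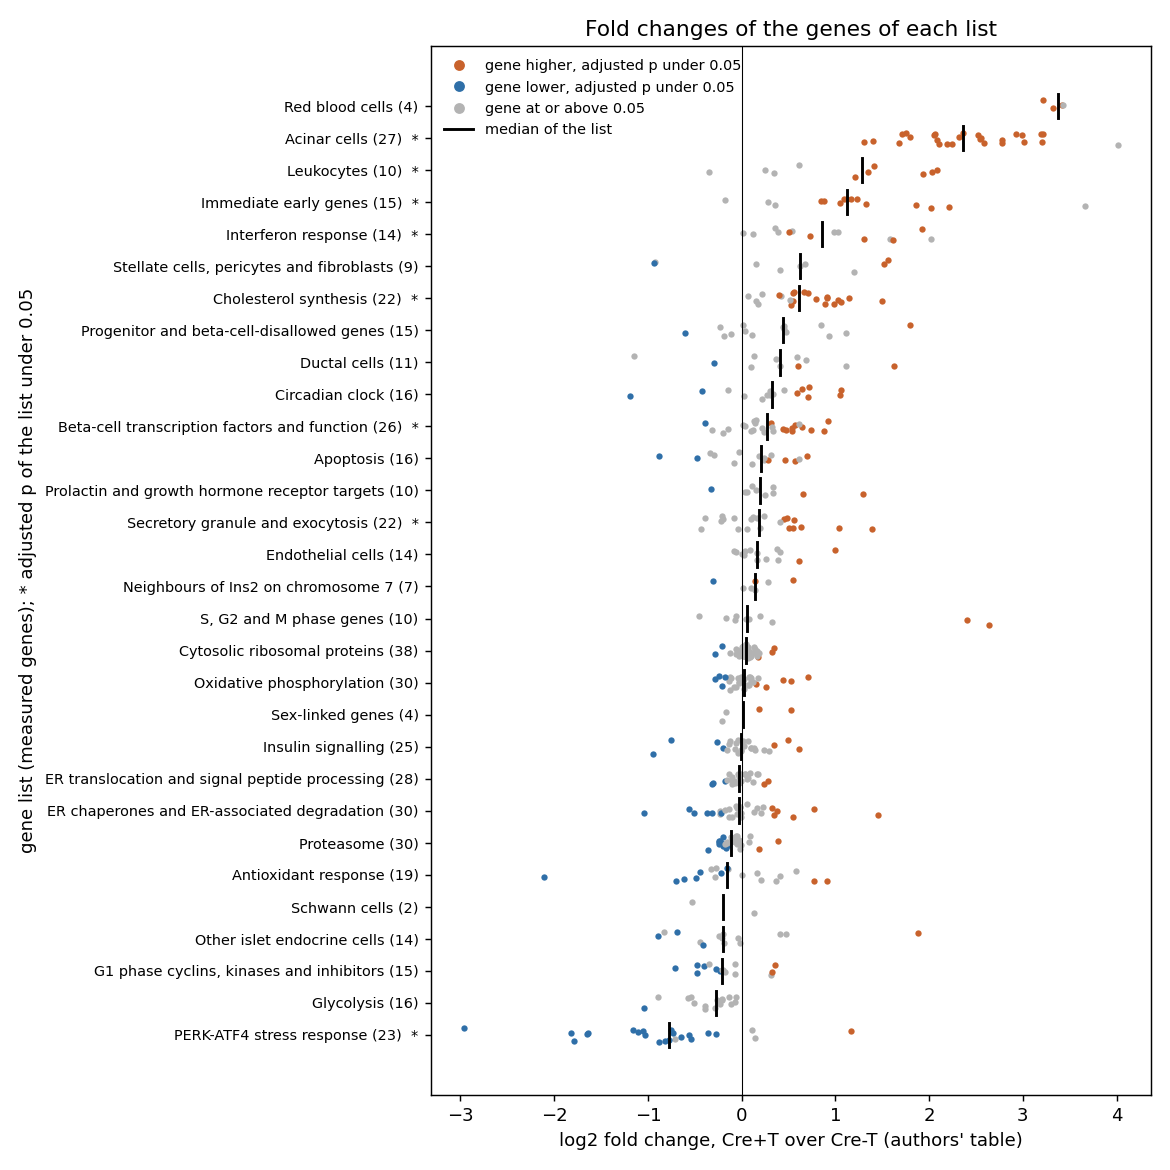
Log2 fold change of Cre+T over Cre-T (horizontal axis) of each measured gene of the 30 lists (vertical axis, ordered by median, number of measured genes in brackets), with 1 point per gene, colour for direction at a limma adjusted p under 0.05, and a bar at each median in the authors' deposited table. The medians run from -0.78 for the PERK-ATF4 list to 3.37 for red blood cell genes, and stars mark the 8 lists with a cameraPR adjusted p under 0.05.

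Most cholesterol synthesis genes were higher. Of 22 measured genes, 16 rose, none fell and 6 did not pass, or 18 and 0 passed adjusted over the list alone in the authors' deposited table (median 0.61, cameraPR adjusted p = 8.1e-09). At an inter-gene correlation of 0.05 the list's cameraPR adjusted p was 3.3e-05. Idi1, isopentenyl diphosphate isomerase, rose by 1.49 ± 0.25, the sterol dehydrogenase gene Nsdhl by 1.03 ± 0.14, and Fdps, farnesyl diphosphate synthase, by 0.56 ± 0.09 in the authors' deposited table. With summed expression made equal, 12 genes of the list were higher and none lower. Markers of acinar cells (median 2.37), leukocytes (1.28) and red blood cells (3.37) were higher in the same comparison in the authors' deposited table.

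Other lists of metabolism and protein turnover had no call as groups in the main test. All 16 glycolysis genes had negative fold changes, but only Pdk1, which inhibits pyruvate dehydrogenase, fell (-1.05 ± 0.36), and 0 passed when adjusted over the list alone in the authors' deposited table (median -0.27, cameraPR adjusted p = 0.20). Under equal summed expression 4 glycolysis genes were lower. The glycolysis list passed with fold change in place of t (adjusted p = 0.013, in a range of 0.013 to 0.72 over the alternatives). Pfkl (-0.89 ± 0.39), Gpi1 (-0.54 ± 0.23) and Aldoa (-0.39 ± 0.19) did not pass in the authors' deposited table. Of 30 genes of oxidative phosphorylation, 5 rose and 4 fell, or 5 and 3 adjusted over the list alone in the authors' deposited table (median 0.03, cameraPR adjusted p = 0.29). Ndufa1 (0.71 ± 0.09), Cox6c (0.44 ± 0.06) and Cox4i1 (0.26 ± 0.05) rose and Sdhb (-0.28 ± 0.07) fell in the authors' deposited table, while with summed expression made equal 4 genes of the list were higher and 13 lower, with a median of -0.12. Among 38 ribosomal protein genes 3 rose and 2 fell, or 2 and 1 adjusted over the list alone in the authors' deposited table (median 0.05, cameraPR adjusted p = 0.20). None was higher and 11 were lower with summed expression made equal, where the median was -0.10. Those past the threshold in the main analysis included Rps14 (0.35 ± 0.09) and Rps27 (0.32 ± 0.09), which rose, and Rps2 (-0.29 ± 0.08), which fell in the authors' deposited table. Processed copies of such genes share their reads, and Rps14 and Rps27 no longer passed with summed expression made equal (adjusted p = 0.068 and 0.11). Of 30 proteasome genes, 2 rose and 11 fell, also when adjusted over the list alone in the authors' deposited table (median -0.12, cameraPR adjusted p = 0.056). Only 1 was higher and 25 were lower with summed expression made equal. The proteasome list passed in 4 of 7 alternatives, with adjusted p between 5.9e-04 and 0.36 over all 7. Psma4 (-0.24 ± 0.05) and Psma7 (-0.23 ± 0.05) fell and Psmd12 (0.38 ± 0.07) and Psma3 (0.19 ± 0.05) rose in the authors' deposited table, Psma3 not passing with summed expression made equal (adjusted p = 0.45).

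Signalling and stress lists were mixed. Of 25 insulin signalling genes, 3 rose and 4 fell, also when adjusted over the list alone in the authors' deposited table, with a median of -0.01 although the test leaned towards higher (cameraPR adjusted p = 0.91). The scaling to equal summed expression gave 2 higher and 11 lower, with a median of -0.15. Irs2, an adaptor of the insulin receptor, rose by 0.61 ± 0.17 and Foxo1 by 0.50 ± 0.10, while the receptor gene Igf1r (-0.95 ± 0.23) and Grb10 (-0.75 ± 0.13), an inhibitor of insulin receptor signalling, fell in the authors' deposited table. Among 16 apoptosis genes 4 rose and 2 fell, also when adjusted over the list alone in the authors' deposited table (median 0.21, cameraPR adjusted p = 0.22). The balance turned round with summed expression made equal, with 2 higher and 4 lower. The survival gene Mcl1 (0.46 ± 0.10) rose, and the pro-apoptotic genes Bax (-0.47 ± 0.10) and Bbc3 (-0.89 ± 0.25) fell in the authors' deposited table. Of 19 antioxidant genes 2 rose and 7 fell, or 2 and 8 adjusted over the list alone in the authors' deposited table (median -0.15, cameraPR adjusted p = 0.37), and 2 were higher and 10 lower with summed expression made equal. Haem oxygenase, Hmox1, was lowest at -2.11 ± 0.47, Gclm (-0.70 ± 0.13) and Gpx4 (-0.44 ± 0.09) fell, and Prdx4, a peroxidase of the endoplasmic reticulum, rose by 0.91 ± 0.12 in the authors' deposited table. Of 10 targets of prolactin and growth hormone receptors, 2 rose and 1 fell, also when adjusted over the list alone in the authors' deposited table (median 0.20, cameraPR adjusted p = 0.11). Matn2 (1.30 ± 0.15) and Cish (0.65 ± 0.16) rose, Ehhadh (-0.32 ± 0.07) fell, and Socs2 (0.25 ± 0.11) did not pass in the authors' deposited table.

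Immediate early genes were higher. Of 15 measured, 11 rose, none fell and 4 did not pass, also when adjusted over the list alone in the authors' deposited table (median 1.12, cameraPR adjusted p = 2.4e-04). Fos rose 4.05-fold (2.02 ± 0.55 log2 units), Ier2 by 1.12 ± 0.26, Junb by 1.09 ± 0.28 and the phosphatase gene Dusp1 by 1.05 ± 0.24 log2 units in the authors' deposited table. Markers of acinar cells (median 2.37), red blood cells (3.37) and leukocytes (1.28) were higher in the same comparison in the authors' deposited table. Of 16 clock genes, 6 rose and 2 fell, also when adjusted over the list alone in the authors' deposited table, with a median of 0.32 and a cameraPR adjusted p of 0.056. The clock list passed in 3 of 7 alternatives, with adjusted p between 0.0068 and 0.18 over all 7. The list test looks for a shift in 1 direction, and genes of this list passed in both. Its missing call in the main test is therefore no sign that clock genes were unchanged. The clock output genes Dbp (1.04 ± 0.20) and Tef (0.72 ± 0.17) and the repressor gene Nr1d2 (0.70 ± 0.17) rose, while Arntl, which encodes the activator BMAL1, was lower at -1.19 ± 0.23 in the authors' deposited table. Of 14 interferon response genes 5 rose and none fell, also when adjusted over the list alone in the authors' deposited table (median 0.86, cameraPR adjusted p = 0.013). The call was lost at an inter-gene correlation of 0.05, with an adjusted p of 0.056, in a range of 4.8e-10 to 0.056 over the alternatives, and leukocyte markers moved the same way. Gbp2 (1.93 ± 0.67), Gbp3 (1.62 ± 0.51), Ddx58 (0.72 ± 0.22) and Irf9 (0.51 ± 0.17) had the smallest p in the authors' deposited table. In this list 3 genes were higher and none lower with summed expression made equal, and Irf9 no longer passed (adjusted p = 0.084).

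Markers of acinar cells, which make the digestive enzymes of the exocrine pancreas, were higher throughout. Of 27 measured, 26 rose and none fell, or 27 and 0 adjusted over the list alone in the authors' deposited table, with a median of 2.37 log2 units and a cameraPR adjusted p of 8.1e-09. At an inter-gene correlation of 0.05 the cameraPR adjusted p was 5.1e-05. Markers of 1 cell type can vary together and their correlation could not be estimated, so both values may be too small. The ribonuclease gene Rnase1 (3.20 ± 0.76), pancreatic lipase Pnlip (3.19 ± 0.77), colipase Clps (2.99 ± 0.75) and carboxypeptidase Cpb1 (2.93 ± 0.73) had the smallest p in the authors' deposited table. The amylase, elastase and trypsinogen genes of this list belong to families of similar copies, so their single values are uncertain. Haemoglobin genes rose as well, 3 of 4 over all genes and 4 of 4 adjusted over the list alone in the authors' deposited table, too few for a list test. Hbb-bs was at 3.22 ± 0.87, beside the alpha-globins above, and Hbb-bt, at 3.42 ± 1.32, did not pass in the authors' deposited table.

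Leukocyte markers were also higher, with 6 of 10 measured rising and none falling, or 7 and 0 adjusted over the list alone in the authors' deposited table (median 1.28, cameraPR adjusted p = 1.3e-04). The class II antigen genes H2-Aa (2.08 ± 0.33) and H2-Ab1 (2.03 ± 0.36), their invariant chain Cd74 (1.35 ± 0.25) and the complement gene C1qa (1.21 ± 0.18) had the smallest p in the authors' deposited table. The class II gene H2-Eb1 (1.94 ± 0.37) and Cd14 (1.42 ± 0.29) also rose. The rise was not shared by all markers. Lyz2 (0.61 ± 0.25), the complement genes C1qb (0.34 ± 0.16) and C1qc (0.24 ± 0.17), and Cd68 (-0.35 ± 0.17) did not pass in the authors' deposited table. Of 11 ductal markers 2 rose and 1 fell, or 2 and 0 adjusted over the list alone in the authors' deposited table (median 0.41, cameraPR adjusted p = 0.26). Tff2 (1.63 ± 0.52) and Ambp (0.60 ± 0.16) rose, the keratin gene Krt7 was lower at -0.29 ± 0.11, and Sox9 is given above in the authors' deposited table. Of 14 endothelial markers 2 rose, or 1 adjusted over the list alone, and none fell in the authors' deposited table (median 0.16, cameraPR adjusted p = 0.22). Plvap rose 1.99-fold and Erg by 0.61 ± 0.22 log2 units, while Cdh5 (0.41 ± 0.20) and Tie1 (0.39 ± 0.22) did not pass in the authors' deposited table; Erg was lost with summed expression made equal (adjusted p = 0.096). Of 9 markers of stellate cells, pericytes and fibroblasts 2 rose and 1 fell, or 1 and 0 adjusted over the list alone in the authors' deposited table (median 0.63, cameraPR adjusted p = 0.31). The pericyte gene Rgs5 (1.51 ± 0.36) and decorin, Dcn (1.56 ± 0.55), rose, Pdgfrb (-0.94 ± 0.35) fell and Acta2 (1.20 ± 0.61) did not pass in the authors' deposited table. The 2 measured Schwann cell genes, Erbb3 (0.13 ± 0.31) and Ngfr (-0.53 ± 0.46), passed neither over all genes nor adjusted over the list alone in the authors' deposited table.

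Of 4 measured genes of the Y chromosome, Ddx3y (0.53 ± 0.17) and Uty (0.19 ± 0.07) rose and Eif2s3y (-0.21 ± 0.14) and Kdm5d (-0.16 ± 0.09) did not pass, also when adjusted over the list alone in the authors' deposited table. Xist and Tsix, the other genes of this sex-linked list, had no row, for a reason that is unknown. Neither Ddx3y nor Uty passed with summed expression made equal (adjusted p = 0.070 and 0.58), where 1 gene of the list was lower. Of 7 measured neighbours of Ins2 on chromosome 7, 2 rose and 1 fell, also when adjusted over the list alone in the authors' deposited table (median 0.15, cameraPR adjusted p = 0.38). The tetraspanin gene Cd81 rose by 0.55 ± 0.12 and Nap1l4 by 0.15 ± 0.05, Mrpl23 fell (-0.30 ± 0.09) and Th (0.28 ± 0.20) did not pass in the authors' deposited table. Nap1l4 was lost with summed expression made equal (adjusted p = 0.97).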

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

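The scalings, the removal of a trend, the authors' q-value and the background without acinar genes were chosen after seeing the data. The counts of higher and lower genes moved by over 1.5 times under these settings: 756 and 1079 at an adjusted p under 0.01, 1096 and 803 among genes at or above the median mean expression, 248 and 130 with a minimum of 1 log2 unit, 32 and 106 with Holm adjustment, and 860 and 3934 with summed expression made equal. The higher count alone did so at the authors' q-value under 0.05 (2700 genes, with 2851 lower). A stricter limit or fewer genes lowers a count by construction. With an adjusted p under 0.1, a mean of at least 1, 1 row per symbol or the ribosomal scaling, counts stayed between 1393 and 2308 for higher and between 2048 and 2591 for lower genes. Ins2 was at -0.61 and -0.51 under the 2 scalings, and its sign, which set the direction of the comparison, is assumed. The main test called 8 lists. At an inter-gene correlation of 0.05 it called 5, losing the beta-cell, granule and interferon lists, and with summed expression made equal it called 15, of which 7 were added (progenitor, ductal, endothelial, stellate, circadian and prolactin lists higher, proteasome lower). Ranks called 10, adding the proteasome and clock lists, and fold change in place of t 12, adding the S, G2 and M phase, progenitor, ductal, stellate and glycolysis lists. Among genes at or above the median mean expression 8 of only 20 lists with enough genes were called, the leukocyte and interferon lists not being tested, and without the acinar genes, whose list then drops out, 7 of 26. The granule list was lost with fold change in place of t (adjusted p = 0.11). Removal of a trend with expression, transcript length and GC content called 7, losing the beta-cell (0.093) and granule (0.26) lists, and adding the proteasome list (0.026). No called list changed direction. With summed expression made equal, the counts of higher and of lower genes moved by at most 1 gene in each list whose counts under this scaling are not given in the report. Lists without a call turned direction in 6 cases: other endocrine cells (0.72), oxidative phosphorylation (0.99) and insulin signalling (0.77) with summed expression made equal, and insulin signalling with fold change in place of t (0.84), among genes at or above the median mean expression (0.48) and with the trend removed (0.59), all adjusted p. For these the cause was not tested. No paired analysis was possible because the table has no values per sample. Not run for the same reason were DESeq2 size factors, refits with other tools, no filter on low counts, the title numbers as a block, leaving out each sample, other scalings from counts and an estimated correlation. Other splits of the samples could not be counted, so chance was judged by the authors' test alone. Of 37 S, G2 and M phase genes 27 had no row, and whether depth, the authors' filter or low expression left them out is unknown.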

Other observations

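The comparisons of acinar, leukocyte and PERK-ATF4 genes with other cell type lists and with the beta-cell lists were chosen after the results were seen. The limits of the other tests were set before the values they measure were seen. The removal of a trend was itself added after the main results were seen. Cytosolic aminoacyl-tRNA synthetases charge tRNAs with amino acids. All 12 that were listed as ATF4 targets fell, from -0.31 for Cars to -0.96 for Mars, with a median of -0.58 in the authors' deposited table (cameraPR adjusted p = 8.6e-12 over 6 added lists). That p-value may be too small, since such genes can vary together. Eprs was at -0.94 with a limma adjusted p of 2.4e-05, rank 6 of all genes in the authors' deposited table. Of 8 other cytosolic synthetases 1 rose and 3 fell (median -0.13, cameraPR adjusted p = 0.074), and of 16 mitochondrial ones 8 fell (median -0.22, cameraPR adjusted p = 0.0041) in the authors' deposited table. The hypothesis of a lower output of ATF4 predicted a larger fall of its targets, and their median minus that of the mitochondrial synthetases was -0.35 in the authors' deposited table (permutation p = 0.0039 over genes, which are not independent). This goes with a lower ATF4 output but also with any other regulator the 12 genes share, which may include factors not tested here.

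Among mitochondrial proteins, the chaperone Hspa9 was at -0.85 ± 0.08, rank 3 of all genes, and the protease gene Lonp1 at -1.08, both lower in the authors' deposited table. Of 13 other mitochondrial chaperones and proteases, Lonp1 included, 6 fell and 1, Clpx, rose in the authors' deposited table (cameraPR adjusted p = 0.012). Their median of -0.10 lay between the limits set in advance for and against a lower programme, so the hypothesis stayed open.

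Acinar markers were higher in Cre+T. A lower share of beta cells would raise markers of all other cell types alike, but the acinar median lay 2.57 log2 units above that of the other endocrine cells (permutation p = 1e-05, the smallest that 100000 permutations can give, over genes). The genes are not independent, so this p-value may be too small. Both medians were known when this comparison was chosen, so it describes them and is no independent test. The beta-cell list, which a lower share of beta cells would lower, had a median of 0.27 in the authors' deposited table. More acinar RNA in Cre+T samples is a candidate explanation: of 11 measured acinar genes outside the list 8 rose, with a median of 1.90 in the authors' deposited table (cameraPR adjusted p = 0.0010). The abundant genes Ctrb1 (1.72) and Amy2a5 (2.77) had means of 12.5 and 11.1 log2 CPM in the authors' deposited table. Purity of the isolated islets and a change in the acinar cells themselves stay open, as does a difference between the title numbers, and values per sample would be needed to tell whether a few samples carry the rise.

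The PERK-ATF4 list was lower in Cre+T. A trend with expression, transcript length and GC content, all known for 23 of its 23 genes, was fitted to fold changes and separately to t. It explained 2.03% of the variance of fold changes and 3.22% of that of t. After its removal from fold changes the list's median was -0.88. After its removal from t the cameraPR adjusted p was 5.0e-13, which may be too small since these genes can vary together. These values argue against the trend as the whole cause. The same removal ended the calls of the beta-cell and granule lists (adjusted p = 0.093 and 0.26), whose medians went to 0.14 and 0.03. Dilution of islet RNA by other cells would lower beta-cell genes as well, but the medians of the granule and beta-cell lists were 0.18 and 0.27 in the authors' deposited table. A response of islet cells to the deletion of Ins2 stays a hypothesis, since the unexplained title numbers are largely confounded with the groups and the effect of CreERT itself cannot be separated from that of the deletion.

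Leukocyte markers were higher in Cre+T as a list, though Lyz2, C1qb, C1qc and Cd68 did not pass. The list's median lay 1.48 log2 units above that of the other endocrine cells (permutation p = 0.0033 over genes, which are not independent). Both medians were known when this comparison was chosen, so it describes them and is no independent test. The beta-cell list, which a lower share of beta cells would lower, had a median of 0.27. These medians argue against a lower share of beta cells as the whole cause. Of 5 measured leukocyte genes outside the list only Ctss rose, and their median of 0.38 (cameraPR adjusted p = 0.12) lay between the limits set in advance, so more leukocyte RNA may or may not be the source. The class II genes H2-Aa, H2-Ab1 and H2-Eb1 lie together on chromosome 17, and strain variants there were not examined. A difference between the title numbers stays open here too.

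The 200 genes with the largest t were not visibly crowded on the genome. The fullest window of 10 Mb held 6 of them, against a median of 5 and a 95th percentile of 7 in 10000 shuffles, 38.0% of which held as many. A stretch of chromosome that came with the Cre transgene could neither be seen nor excluded by this test.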
